A study of Mus musculus with 6 samples.

How the data were processed

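Polyadenylated RNA of primary mouse vascular smooth muscle cells was sequenced by the authors in 6 libraries, 3 from cells transfected with a scrambled siRNA and 3 from cells transfected with siRNA against Sirt7 (20 nM, 48 h). Per the submitters' processing notes, the authors aligned reads with HISAT2 to the mouse genome (GRCm38, mm10), and the deposited values are FPKM, 1 value per annotated transcript and library. The aligner's version, the program that estimated FPKM, the annotation release, the treatment of reads shared by similar genes and the siRNA sequences are not given in the sources used here. The table holds 23242 transcripts of 11808 gene identifiers, of 1 transcript type (protein coding), and each has a group mean above 0.5 FPKM in at least 1 group, so genes low in both groups were not analysed here. A check for steps of whole reads in the values found none, so depth and counting error are unknown. Groups were taken from the sample titles, whose spelling of the control siRNA was read as scrambled.

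Transcript values were summed to genes, and 10854 genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) at the deposited scaling with limma 3.58.1 (trend and robust options) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Lists of 28 gene groups and 10 cell type markers were tested with camera (preset correlation 0.01, two-sided) where at least 5 members were tested, 31 lists in all, with adjustment over those lists, and beside it with an estimated correlation and with fry. The groups were contractile and synthetic smooth muscle, collagen and matrix, matrix proteases, osteogenic genes, calcification inhibitors, mitosis, DNA replication, p53 targets, ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, the mitochondrial unfolded protein response, endoplasmic reticulum stress, interferon-stimulated genes, NF-kB targets, hypoxia, glycolysis, sterols, lipids, TGF-beta, NRF2, autophagy, sirtuins, YAP and SRF, Wnt and Notch, and histones. The markers were those of smooth muscle, endothelium, macrophages, adventitial fibroblasts, lymphocytes, adipocytes, Schwann cells, mesothelium, skeletal and cardiac muscle, and erythroid cells. Lists, the tests of genes and lists, the rule for named genes and the alternatives, except the last of those given below, were fixed before the data were examined. The rule took Sirt7 and the other sirtuins, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose higher mean was at least 5 FPKM, and from each list up to 3 called members with the smallest adjusted p or, where none was called, the member with the highest mean. Gene models with provisional names were counted but not named. The result of 1 gene that the rule takes is not reported here.

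For sequence words, 3' UTRs of the GENCODE vM21 annotation (GRCm38) were matched to 10335 of the tested genes (at least 50 bases). Only the 3' UTR of each gene's most abundant listed transcript was searched. The log2 fold change was regressed on the presence of each of 15265 words of 7 bases, with 3' UTR length and composition as covariates. It was set against 100 shuffles of the fold changes over genes (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, and matplotlib 3.10.9 for plots). Alternatives were median-of-ratios scaling, quantile normalization, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 0.5, limma without the trend and robust options, the replicate number as a block, single transcripts in place of gene sums, each library left out in turn and, chosen after the words were seen, leaving out genes that hold them. The last of these also leaves out genes with no matched 3' UTR. Single-transcript values of a named gene are those of its most abundant tested transcript. The test was tried on simulated data with 200 changed genes among 10854, drawn independently of each other. It recovered 62.7% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 97.0% of those changed 4-fold. Of 170 calls, 9 were false (5.29%). More genes were called in the data, mostly with smaller changes, so these rates need not hold there. In simulated list data, 1 changed list was called and 0 others. Genes were drawn independently there too, so the effect of correlation between genes on the list test was not tried.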

Results

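Vascular smooth muscle cells, the contractile cells of the arterial wall, were isolated from male C57BL/6 mice, grown as primary cultures in normal growth medium and profiled by mRNA sequencing 48 h after transfection with 20 nM of a scrambled control siRNA (siScrambled) or of siRNA against Sirt7 (siSirt7). Sirt7 encodes a NAD-dependent deacylase that lies mainly in the nucleolus, and the comparison asks which transcripts differ when it is depleted. There were 3 libraries in each group. The deposited values are FPKM for 23242 protein-coding transcripts of 11808 genes, and they summed to between 321944 and 333683 FPKM per library. Sequencing depth is unknown, because the table holds no read counts. The labels do not say whether the 3 libraries of a group came from separate isolations, so each p-value measures the spread between these libraries, which may be technical. Below, levels are FPKM summed over the transcripts of a gene, given as mean ± SD with n = 3 per group, and log2 fold changes are siSirt7 over siScrambled on the log2(FPKM + 1) scale, which understates changes of low genes.

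Sirt7 (ENSMUSG00000025138.14, chromosome 11, 120618372 to 120625014, minus strand, GRCm38) was lower in each siSirt7 library than in any siScrambled library. Its level was 4.13 ± 0.50 FPKM (SD, n = 3) with siScrambled, from 3.56 to 4.48, and 0.86 ± 0.45 FPKM (SD, n = 3) with siSirt7, from 0.36 to 1.25. This was a 4.82-fold lower mean and a log2 fold change of -1.49 (SE 0.20, 95% interval -1.98 to -1.004, limma adjusted p = 0.00388). Of the 7 sirtuins, 0 rose and 1, Sirt7, fell, with 1 lower adjusted over the list alone. Sirt1, Sirt2, Sirt3, Sirt5 and Sirt6 had log2 fold changes of -0.14, 0.16, 0.05, 0.11 and 0.08, with adjusted p from 0.153 to 0.923, and Sirt4, at 1.14 and 0.81 FPKM, was below the level tested. The median log2 fold change of the sirtuin list was 0.06 while its mean was -0.20 and its test pointed down (camera adjusted p = 0.823). The most abundant Sirt7 transcript tested alone had a log2 fold change of -1.30 and an adjusted p of 0.0697.

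**Figure D1:**
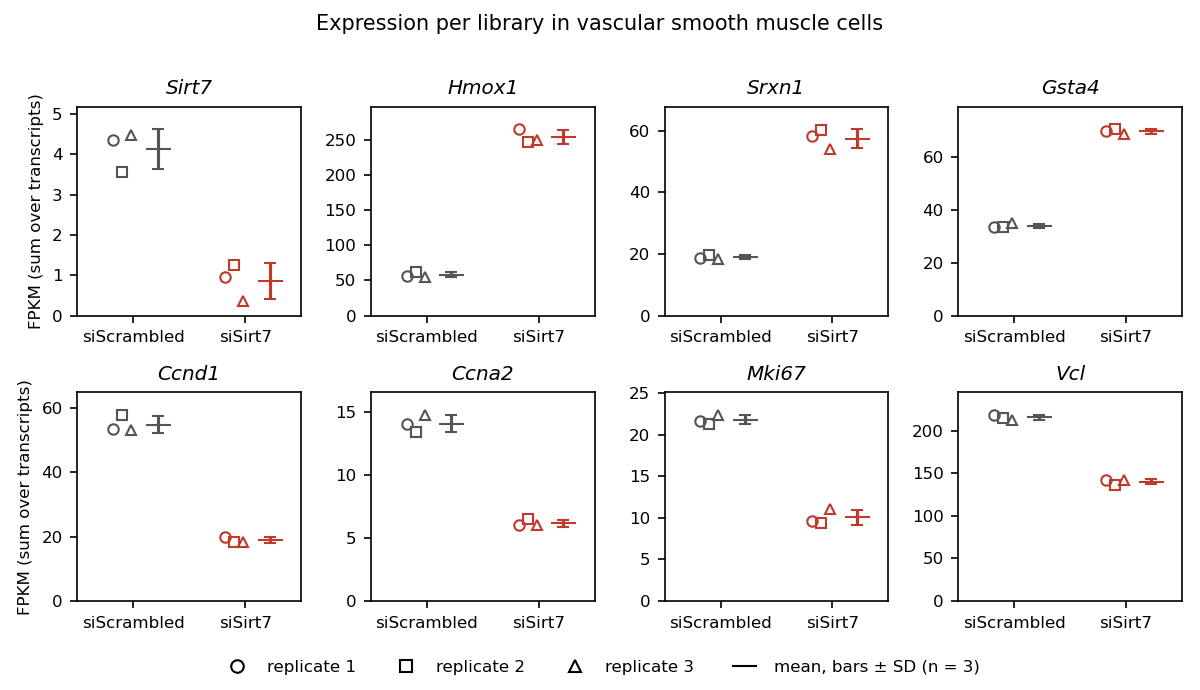
FPKM summed over transcripts for 8 genes in each of the 3 siScrambled and 3 siSirt7 libraries (symbols, 1 per replicate), with group means and SD bars and each y axis starting at 0. The siSirt7 libraries lie below the siScrambled libraries for Sirt7, Ccnd1, Ccna2, Mki67 and Vcl and above them for Hmox1, Srxn1 and Gsta4, with Hmox1 rising from 58.1 to 253.8 FPKM.

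The genes that rose most in the siSirt7 libraries included enzymes against oxidative and electrophile stress, and those that fell most included the G1 cyclin Ccnd1. Gsta3, a glutathione S-transferase, went from 4.24 ± 0.30 to 22.5 ± 1.05 FPKM (SD, n = 3; log2 fold change 2.17, limma adjusted p = 7.6e-05). Hmox1 (chromosome 8, 75093621 to 75100589, plus strand), the inducible heme oxygenase, went from 58.1 ± 3.57 to 253.8 ± 10.0 FPKM (log2 fold change 2.11, SE 0.05, adjusted p = 4.14e-05). Lgals3, the lectin galectin-3, rose 4.92-fold, the retinoic acid binding protein Crabp2 6.51-fold, the pentose phosphate enzyme Taldo1 3.86-fold, the metallothionein Mt2 3.73-fold, the secreted neuropeptide precursor Vgf 5.36-fold, the collagen gene Col5a3 3.77-fold and the sulfiredoxin Srxn1 3.04-fold, with adjusted p from 4.14e-05 to 0.00105. The Vgf transcript tested alone had an adjusted p of 0.0508. Elobl rose 4.53-fold but resembles Elob (233.0 and 225.9 FPKM, adjusted p = 0.630, chosen after its values were seen), and how shared reads were divided is not given in the sources used here. The same doubt holds for the glutathione S-transferases and metallothioneins, whose family members are alike in sequence.

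Among the 10 largest falls, Ccnd1 (chromosome 7) encodes cyclin D1 and went from 54.8 ± 2.70 to 18.8 ± 0.93 FPKM (SD, n = 3; log2 fold change -1.49, SE 0.06, limma adjusted p = 7.6e-05). Frmd4b, a scaffold protein gene, fell 8.10-fold from 6.07 ± 0.41 to 0.75 ± 0.70 FPKM (adjusted p = 0.00346). Rgs4, which dampens G protein signalling, fell 3.10-fold, the sterol sensor regulator Insig2 2.97-fold, the peroxidasin Pxdn 2.57-fold, Parp8 3.29-fold, Pgap2 3.03-fold and Sema6d 3.16-fold, with adjusted p from 0.000103 to 0.000731. Psd3 (log2 fold change -1.41, adjusted p = 0.0457) and Zdhhc21 (-1.32, adjusted p = 0.0335) each lost their call without some libraries and under other settings. Psd3 had adjusted p of 0.126, 0.127, 0.0887 and 0.0982 without siScrambled replicate 2, siScrambled replicate 3, siSirt7 replicate 1 and siSirt7 replicate 2, and from 0.052 to 0.0660 with pseudocounts of 0.1 and 0.5, quantile normalization and no trend and robust options, with 0.570 for its main transcript. Zdhhc21 had adjusted p of 0.0909, 0.0891, 0.0856 and 0.0537 without siScrambled replicates 1, 2 and 3 and siSirt7 replicate 2, 0.0565 with a pseudocount of 0.1 and 0.0549 with the replicate number as a block.

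In all, 2736 of the 10854 genes tested (25.2%) differed between the groups, 1380 higher and 1356 lower with siSirt7, and 106 of them differed at least 2-fold on the fitted scale, 46 higher and 60 lower. The median size of the log2 fold change of the 2736 genes was 0.40, and the median over all tested genes was -0.005. The 2 groups did not overlap for 4770 genes (44.0%), against 10% expected by chance for 3 against 3, and this held for each of the 2736. An unadjusted p under 0.05 was reached by 4111 genes. The number lower was 900 without siScrambled replicate 2, and with single transcripts tested in place of gene sums 1493 genes were called, 780 of them higher and 729 lower in at least 1 transcript. The number changed at least 2-fold was 216 with a pseudocount of 0.1.

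Genes with certain short sequences in their 3' UTR had lower median fold changes than genes without them, and part of them were called lower. Over the 10335 tested genes with a matched 3' UTR, the 7-base word most strongly tied to lower fold changes was ATATGTA, held by 1616 genes (t = -19.6 in a regression with 3' UTR length and base composition, against -5.10 for the strongest word in 100 shuffles). The median log2 fold change was 0.03 (SD over genes 0.32) in the 6618 genes without TATGTA, which may hold CGGAGAA, a word described below. It was 0.01 (0.31) in 1355 genes with TATGTA and no longer word and -0.05 (0.31) in 746 genes with TATGTAA but not ATATGTA. It was -0.11 (0.32) in 1044 genes with ATATGTA but not ATATGTAA, and -0.23 (0.36) in 572 genes with ATATGTAA. Of the ATATGTAA genes, 228 (39.9%) were called lower and 29 higher. Of those with ATATGTA but not ATATGTAA, 250 (23.9%) were lower and 70 higher. Of those without TATGTA, 555 (8.39%) were lower and 986 higher. ATATGTA or TATGTAA was present in 598 of 1317 lower genes (45.4%), 168 of 1339 higher genes (12.5%) and 1596 of 7679 genes not called (20.8%). ATATGTA occurs 1 time in the main Sirt7 transcript, in the coding part of exon 6 of 10 (chromosome 11, 120620964 to 120620970), while TATGTAA, and so ATATGTAA, is in none of its annotated transcripts. The word most strongly tied to higher fold changes was CGGAGAA (t = 9.65, against 4.94 in the shuffles), with a median of 0.15 (SD 0.43) over 227 genes. Of these genes, 74 were called higher and 17 lower, and the word is absent from the annotated Sirt7 transcripts. Of the genes named above, Rgs4, Insig2, Pxdn and Zdhhc21 hold ATATGTA, Frmd4b, Ccnd1, Parp8, Psd3 and Pgap2 hold neither ATATGTA nor TATGTAA, Sema6d has no matched 3' UTR, and Gsta3, Taldo1 and Rgs4 hold CGGAGAA. Only the 3' UTR of the most abundant transcript was searched, which has 94 bases for Psd3 and 280 for Parp8. The words were chosen after the values were seen, and genes are not independent replicates. Without the genes that hold ATATGTA, TATGTAA or CGGAGAA and those with no matched 3' UTR, 7804 genes were tested and 1670 called, 1024 higher and 646 lower, 63 of them at least 2-fold.

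**Figure D2:**
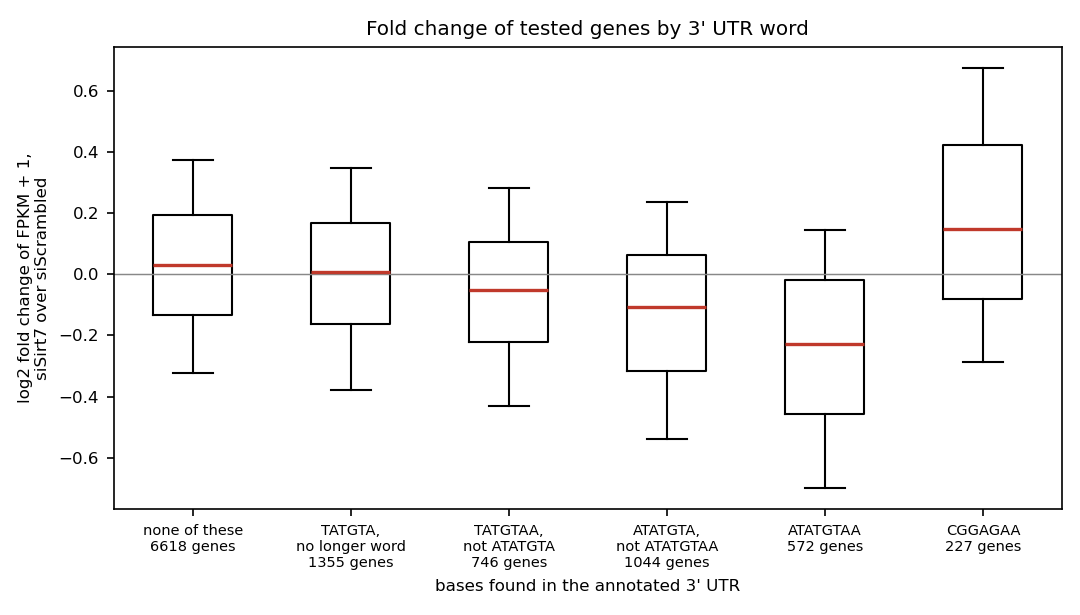
Log2 fold change (siSirt7 over siScrambled, on FPKM + 1) of tested genes grouped by the longest of the listed words in their annotated 3' UTR, with the CGGAGAA group overlapping the others. Red lines are medians, boxes the middle 50% of genes and whiskers the 10th and 90th percentiles. Medians go from 0.03 without TATGTA (marked none of these) to -0.23 with ATATGTAA.

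Genes of cell division fell together. All 20 members of the mitotic list were lower with siSirt7 (0 higher and 20 lower, also adjusted over the list alone), with a median log2 fold change of -0.87. The proliferation marker Mki67 went from 21.8 ± 0.55 to 10.1 ± 0.89 FPKM, cyclin A2 (Ccna2) from 14.1 ± 0.69 to 6.19 ± 0.27 and the mitotic kinesin Kif20a from 11.4 ± 0.19 to 6.00 ± 0.33 (SD, n = 3), with limma adjusted p from 0.00026 to 0.000485. The list's camera adjusted p was 1.66e-13, and adjusted p = 0.136 with an estimated correlation. Of 19 tested members of the DNA replication and G1/S list, 15 were lower and 0 higher, also adjusted over the list alone, with a median of -0.46 (camera adjusted p = 1.69e-08, adjusted p = 0.184 with an estimated correlation). Besides Ccnd1, these included the helicase subunit Mcm5 (6.44 ± 0.06 to 2.64 ± 0.31 FPKM) and the ribonucleotide reductase subunit Rrm2 (12.3 ± 0.60 to 7.09 ± 0.46 FPKM). ATATGTA or TATGTAA was present in 6 of the 20 mitotic genes, Kif20a among them, and in 5 of the 19 replication genes, Mcm5 among them, while 14 mitotic genes without either word had a median of -0.87. With transcripts tested alone, the main Kif20a transcript had a log2 fold change of 1.30 (adjusted p = 0.562) and that of Mcm5 -0.79 (adjusted p = 0.0919). Of 19 p53 targets and cell cycle inhibitors, 2 were higher and 5 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.400). The p53 targets Ccng1 and Ei24 rose 1.34-fold and 1.86-fold and the receptor Eda2r fell 1.44-fold. Cdkn2a (-0.40), Cdkn2b (-0.44), Perp (-0.32) and Sesn2 (-0.23) also fell and were, like the next gene, chosen after their values were seen, while the cell cycle inhibitor Cdkn1a was at 106.9 ± 0.54 and 109.6 ± 3.25 FPKM (adjusted p = 0.481). Ei24 holds CGGAGAA, and its main transcript alone had an adjusted p of 0.171. Of 4 replication-dependent histone genes tested, 2 were higher (3 adjusted over the list alone), Hist1h2bc 1.23-fold and Hist1h1c 1.20-fold, with no list test because of their number and with reads that near-identical histone genes could share. The libraries hold polyadenylated RNA, so histone transcripts without a poly(A) tail were not measured.

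Most measured genes of the NRF2 list, many of them antioxidant genes that this transcription factor is known to induce, rose. Of the 20 members of the NRF2 antioxidant and ferroptosis list, 14 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.75. Besides Hmox1, Srxn1 went from 18.9 ± 0.60 to 57.5 ± 3.06 FPKM and the glutathione S-transferase Gsta4 from 33.9 ± 0.81 to 69.5 ± 0.91 FPKM (SD, n = 3; limma adjusted p = 7.6e-05 for each). Among members chosen after their values were seen, the quinone reductase Nqo1 rose 2.79-fold, the glutathione synthesis enzyme Gclc, with TATGTAA, 2.00-fold and catalase (Cat) 1.80-fold, and Acsl4, which favours ferroptosis, fell 1.26-fold. Superoxide dismutase Sod1 (240.9 and 240.3 FPKM, adjusted p = 0.943) and Gpx4 (162.3 and 167.2 FPKM, adjusted p = 0.713) were not called. The list's camera adjusted p was 2.09e-09, and adjusted p = 0.0676 with an estimated correlation. Of 20 autophagy and lysosome genes, 8 were higher and 0 lower (10 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00265, adjusted p = 0.273 with an estimated correlation). The autophagy receptor Sqstm1 went from 182.2 ± 4.69 to 340.8 ± 14.8 FPKM, and Atg12 and Gabarapl1 rose 1.36-fold and 1.32-fold. The main transcripts of Sqstm1 and Gabarapl1 tested alone had adjusted p of 0.249 and 0.0503.

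**Figure D3:**
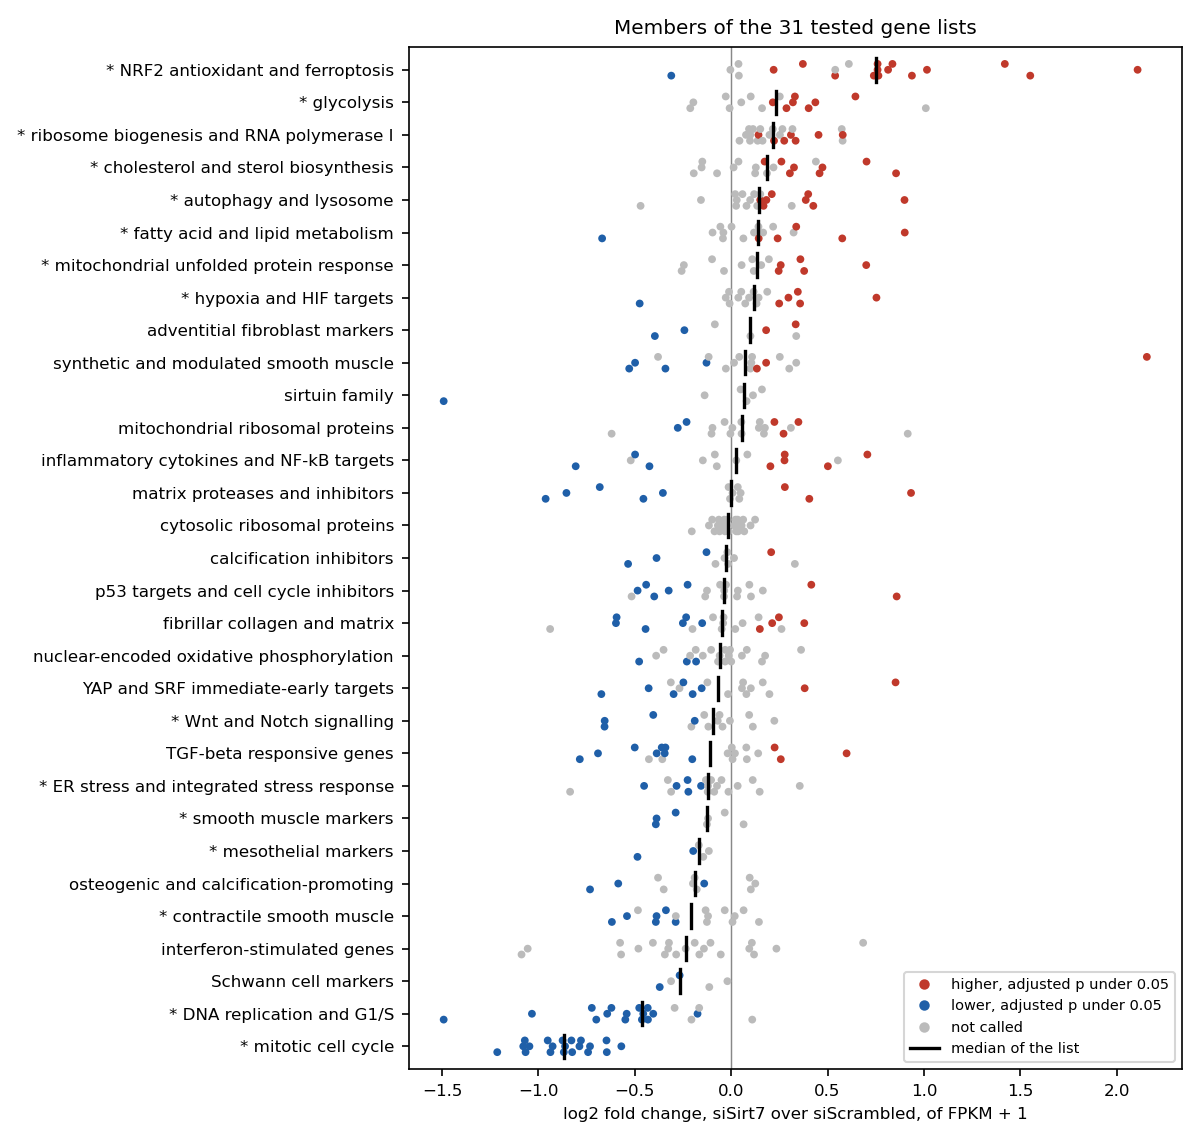
Log2 fold change (siSirt7 over siScrambled, on FPKM + 1) of each tested member (points, coloured by call) of the 31 gene lists with at least 5 tested members, with black bars for list medians and an asterisk at the 15 lists whose camera adjusted p was under 0.05. The mitotic list lies at a median of -0.87 with each of its 20 members lower, and the NRF2 list at 0.75.

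Contractile genes of smooth muscle fell modestly and in part. Of 16 tested members of the contractile list, 6 were lower and 0 higher (9 and 1 adjusted over the list alone), with a median log2 fold change of -0.21 (camera adjusted p = 0.00125, adjusted p = 0.273 with an estimated correlation). The actin anchor vinculin (Vcl) went from 215.9 ± 2.99 to 140.2 ± 3.11 FPKM, tropomyosin Tpm1 from 712.1 ± 20.7 to 489.2 ± 14.03 and transgelin (Tagln) from 958.1 ± 1.03 to 784.9 ± 31.9 (SD, n = 3; limma adjusted p from 0.000149 to 0.00243). Smooth muscle actin (Acta2, 1363 ± 5.55 and 1333 ± 74.2 FPKM, adjusted p = 0.603) and smooth muscle myosin (Myh11, 78.7 ± 4.01 and 72.0 ± 2.94 FPKM, adjusted p = 0.122), chosen after their values were seen, were not called. ATATGTA or TATGTAA was present in 5 of the 16 contractile genes, Vcl, Tpm1 and Cnn1 among them, and 3 of the 11 without either word were lower. Of 7 smooth muscle markers, 3 were lower and 0 higher (4 and 0 adjusted over the list alone, camera adjusted p = 0.0159, adjusted p = 0.288 with an estimated correlation): Tagln, calponin (Cnn1), which fell 1.32-fold, and smoothelin (Smtn), which fell 1.31-fold. With single transcripts the list's adjusted p was 0.176 and that of the main Smtn transcript 0.411. The list of synthetic and modulated smooth muscle genes went both ways, with 3 of 18 higher and 4 lower (6 and 5 adjusted over the list alone), a median of 0.07 and a camera adjusted p of 0.580. Lgals3 rose 4.92-fold, while the adhesion molecule Vcam1 (142.8 ± 2.82 to 100.8 ± 0.58 FPKM, ATATGTA present) and the non-muscle myosin Myh10 (235.6 ± 1.57 to 185.9 ± 7.93 FPKM, main transcript alone adjusted p = 0.132) fell. Lum (0.18) and Tpm4 (0.13) were also higher and Klf4 (-0.53) and Tnfrsf11b (-0.13) also lower, of which Tpm4 and Klf4 were chosen after their values were seen.

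Matrix genes and their regulators also went both ways. Of 20 fibrillar collagen and matrix genes, 4 were higher and 6 lower, with equal numbers adjusted over the list alone (camera adjusted p = 0.385). Thrombospondin 1 (Thbs1) went from 1270 ± 7.2 to 932.9 ± 9.68 FPKM and the collagen cross-linking enzyme Lox from 782.5 ± 15.0 to 517.9 ± 16.6, while Col3a1 went from 561.2 ± 8.74 to 730.7 ± 30.8 (SD, n = 3; limma adjusted p from 0.000143 to 0.00115). Col1a2 (0.15), Col5a2 (0.21) and Col6a1 (0.25) also rose and were chosen after their values were seen. Among 14 matrix proteases and inhibitors, 3 were higher and 5 lower, with equal numbers adjusted over the list alone. The protease Adamts1 fell from 89.3 ± 0.90 to 45.4 ± 1.42 FPKM and the inhibitor Timp2 from 432.8 ± 5.10 to 269.4 ± 6.73, and Timp3 rose from 777.7 ± 8.89 to 1030 ± 6.02. Mmp3 (0.93) and Ctsk (0.28) also rose and Plau (-0.85), Mmp14 (-0.46) and Mmp19 (-0.35) also fell, all chosen after their values were seen. That list's median was 0.0005 and its mean -0.11, its test pointed down (camera adjusted p = 0.385), and its median was -0.02 after quantile normalization. Thbs1, Lox, Adamts1, Timp2 and Timp3 hold ATATGTA. Of 20 TGF-beta responsive genes, 3 were higher and 8 lower, with equal numbers adjusted over the list alone (median -0.11, camera adjusted p = 0.182, and 0.0468 with single transcripts). The growth factor genes Ctgf and Tgfb3 fell 1.27-fold and 1.29-fold and the repressor Bhlhe40, with ATATGTA, rose 1.54-fold, and the other risers, Ski (0.26) and Tgfbr2 (0.23), were chosen after their values were seen. Of 18 YAP and SRF immediate-early targets, 2 were higher and 6 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.264), among them Egr1 and Cyr61, which fell 1.63-fold and 1.15-fold, and Fosl1, which rose 1.90-fold, beside Myc (0.38, chosen after its values were seen). Of 14 Wnt and Notch genes, 4 were lower and 0 higher, also adjusted over the list alone (median -0.09, camera adjusted p = 0.0389, adjusted p = 0.237 with an estimated correlation). These were the secreted Wnt pathway proteins Dkk3, Wisp1 and Sfrp2, which fell 1.59-fold, 1.59-fold and 1.33-fold, and Nkd1 (-0.19, chosen after its values were seen). The list's adjusted p was 0.0675 without siScrambled replicate 1 and 0.0601 without siSirt7 replicate 2. It was 0.417 without the genes holding the 3' UTR words, Dkk3 among them, and those with no matched 3' UTR, Wisp1 among them. At most 7 of the 14 genes remained in that setting, so the change cannot be laid to the words alone.

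Vascular smooth muscle cells can take on bone-like features, for which lists of promoting and inhibiting genes were compared. Of 11 osteogenic and calcification-promoting genes, 3 were lower and 0 higher, also adjusted over the list alone. The list's median was -0.19 (camera adjusted p = 0.101, and 0.0458 without the genes holding the 3' UTR words, fry adjusted p = 0.00158). The cartilage regulator Sox9 went from 10.6 ± 0.45 to 6.75 ± 0.23 FPKM (SD, n = 3; limma adjusted p = 0.00157) and Bmp4 fell 1.10-fold. The Wnt inhibitor Sost fell 2.49-fold from a low level, 2.03 ± 0.42 to 0.82 ± 0.11 FPKM (limma adjusted p = 0.0103, and 0.0529 for its transcript tested alone). The list groups Sost with promoting genes although it encodes an inhibitor, so the 3 lower genes cannot be read as 3 lost promoters. Bmp4 had adjusted p from 0.0597 to 0.0881 without each library other than siSirt7 replicate 2, 0.0811 without the trend and robust options and 0.0841 for its main transcript. Of 10 calcification inhibitors, 1 was higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.580). Gas6 rose 1.16-fold, the BMP antagonist Grem1 fell 1.46-fold, Vdr (chosen after its values were seen) had a log2 fold change of -0.39, and osteoprotegerin (Tnfrsf11b) fell 1.09-fold, with adjusted p of 0.0751 and 0.0767 without siScrambled replicates 2 and 3 and 0.089 without the trend and robust options.

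Some genes of ribosome assembly rose, those of cytosolic ribosomal proteins were not called, and a few of mitochondrial ribosomal proteins went either way. Of 23 ribosome biogenesis and RNA polymerase I genes, 7 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.22 (camera adjusted p = 0.000177, adjusted p = 0.136 with an estimated correlation). The nucleolar proteins Npm1 and Ncl, the latter with TATGTAA, went from 451.9 ± 4.25 to 570.1 ± 13.3 and from 125.3 ± 2.63 to 155.6 ± 0.94 FPKM, and the RNA polymerase I initiation factor Rrn3, which holds CGGAGAA, from 16.2 ± 0.67 to 24.7 ± 0.59 (SD, n = 3; limma adjusted p from 0.00067 to 0.00102). By limma, 0 of 24 cytosolic ribosomal protein genes were called, also adjusted over the list alone, and 1 had an unadjusted p under 0.05, with a median of -0.02 (camera adjusted p = 0.934, fry adjusted p = 0.913), and Rplp1 was at 1326 ± 8.83 and 1301 ± 138.4 FPKM. Of 19 mitochondrial ribosomal protein genes, 3 were higher and 2 lower, with equal numbers adjusted over the list alone (camera adjusted p = 0.385): Mrpl40 rose 1.29-fold, Mrpl16 fell 1.18-fold and Mrpl45 rose 1.18-fold. Mrps10 (0.27) and Mrpl20 (-0.28) were chosen after their values were seen. Mrpl45 had adjusted p from 0.0614 to 0.0866 without each library other than siSirt7 replicate 3 and 0.0699 for its main transcript, and with the replicate number as a block Mrpl16 had 0.0555 and Mrpl45 0.0635. Of 21 nuclear-encoded oxidative phosphorylation genes, 3 were lower and 0 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.209, and 0.0435 after quantile normalization). Sdhb, with ATATGTA, fell 1.41-fold, and Cox6c and Ndufa4 fell 1.17-fold and 1.14-fold. The latter genes had adjusted p from 0.0582 to 0.0855 for Cox6c and from 0.0527 to 0.130 for Ndufa4 without each library other than siSirt7 replicate 1. Without the trend and robust options these were 0.0545 and 0.0855, and for the main transcripts 0.0808 and 0.108.

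Some genes of the mitochondrial unfolded protein response rose, and some of the endoplasmic reticulum stress list fell. Of 14 genes of the mitochondrial unfolded protein response, 5 were higher and 0 lower (7 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0166, adjusted p = 0.184 with an estimated correlation). The chaperone Hspd1 went from 147.1 ± 5.54 to 239.8 ± 10.0 FPKM, Hspa9 from 203.5 ± 0.48 to 264.9 ± 0.55 and the protease Lonp1 from 33.0 ± 0.77 to 42.6 ± 1.73 (SD, n = 3; limma adjusted p from 0.000297 to 0.00288). Hspe1 (0.25) and Trap1 (0.26) were chosen after their values were seen. Of 20 genes of the endoplasmic reticulum stress and integrated stress response list, 5 were lower and 0 higher (7 and 2 adjusted over the list alone, median -0.12, camera adjusted p = 0.032, adjusted p = 0.273 with an estimated correlation). The chaperone Hsp90b1 fell 1.17-fold, Sdf2l1 1.41-fold and the serine synthesis enzyme Phgdh 1.116-fold. Creld2 (-0.28) and Sesn2 (-0.23) were chosen after their values were seen. Phgdh had adjusted p of 0.057, 0.0511 and 0.0609 without siScrambled replicates 1, 2 and 3 and 0.0543 without the trend and robust options. The list's adjusted p was 0.0533 without siScrambled replicate 3 and 0.0682 without siSirt7 replicate 3.

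Some sterol, glycolytic and lipid genes rose. Of 19 cholesterol and sterol biosynthesis genes, 8 were higher and 0 lower (9 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.00364, adjusted p = 0.184 with an estimated correlation). The farnesyl diphosphate synthase Fdps went from 40.2 ± 0.43 to 66.1 ± 2.08 FPKM and Insig1, which holds CGGAGAA, from 18.7 ± 1.39 to 34.7 ± 1.61 (SD, n = 3; limma adjusted p = 0.000189 and 0.0006). Of 16 glycolysis genes, 7 were higher and 0 lower, also adjusted over the list alone (median 0.23, camera adjusted p = 0.00364, adjusted p = 0.184 with an estimated correlation), among them Pkm, Pgam1 and Aldoa, which rose 1.32-fold, 1.25-fold and 1.26-fold. Of 17 fatty acid and lipid genes, 5 were higher and 1 lower (9 and 1 adjusted over the list alone, median 0.14, camera adjusted p = 0.0447, adjusted p = 0.474 with an estimated correlation). The elongase Elovl6 rose 2.02-fold and the dehydrogenase Acadl 1.19-fold, Pparg, Scd1 (0.34) and Scd2 (0.14) were also higher, the last 2 chosen after their values were seen, and lipoprotein lipase (Lpl), with ATATGTA or TATGTAA, fell 1.63-fold. This list had adjusted p of 0.0784, 0.0655, 0.103 and 0.0645 without siScrambled replicate 1, siScrambled replicate 2, siSirt7 replicate 2 and siSirt7 replicate 3, and 0.152, 0.108 and 0.109 with the stricter filter, quantile normalization and single transcripts. Of 17 hypoxia and HIF targets, 5 were higher and 1 lower, also adjusted over the list alone (median 0.12, camera adjusted p = 0.0399, adjusted p = 0.41 with an estimated correlation). Ndrg1 rose 1.72-fold, the peptide hormone gene Adm rose 1.29-fold, Bnip3 (0.30), Vegfa (0.25) and Egln3 (0.35) were chosen after their values were seen, and Ddit4 fell 1.43-fold. The hypoxia list had adjusted p of 0.0784, 0.0743 and 0.0825 without siScrambled replicate 1, siScrambled replicate 3 and siSirt7 replicate 1, of 0.152, 0.083 and 0.0881 with those 3 settings, and of 0.0811 without the genes holding the 3' UTR words, where its median was 0.14.

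Inflammatory genes went both ways and interferon-stimulated genes varied within groups. Of 15 inflammatory cytokine and NF-kB target genes, 5 were higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.934), with a median of 0.03 that was -0.01 after quantile normalization. The chemokine Ccl7 went from 9.80 ± 1.21 to 16.6 ± 0.55 FPKM and its neighbour Ccl2 from 40.1 ± 2.18 to 22.5 ± 0.43 (SD, n = 3; limma adjusted p = 0.00292 and 0.000318). Vcam1 also fell, and Csf1 (0.20), Icam1 (0.28), Il1rn (0.50) and Il6 (0.28), which rose, and Ptgs2 (-0.42), which fell, were chosen after their values were seen. By limma, 0 of 21 interferon-stimulated genes were called, also adjusted over the list alone, and 4 had an unadjusted p under 0.05, with a median of -0.24 (camera adjusted p = 0.183, and 0.00376 without siScrambled replicate 3, fry adjusted p = 0.476). Isg15 was at 86.1 ± 35.0 and 68.2 ± 17.8 FPKM (adjusted p = 0.583).

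Some markers of other cell types were well expressed and fell, among them the mesothelial marker Upk1b and the muscle marker Tnnt2. Of the mesothelial markers, 2 of 5 tested were lower and 0 higher, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0401, adjusted p = 0.344 with an estimated correlation). Upk1b, with ATATGTA, went from 126.5 ± 2.65 to 90.1 ± 4.48 FPKM and Upk3b from 38.2 ± 0.78 to 33.2 ± 0.94 (SD, n = 3; limma adjusted p = 0.000951 and 0.0147). Upk3b had adjusted p of 0.0567 and 0.0503 without siScrambled replicate 2 and siSirt7 replicate 2. This list had adjusted p of 0.0675, 0.0802 and 0.061 without siScrambled replicate 1, siSirt7 replicate 2 and siSirt7 replicate 3, and of 0.115 and 0.0514 with no filter and with single transcripts. Of 7 adventitial fibroblast markers, 2 were higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.549): Mfap5 rose 1.27-fold, Lum rose 1.14-fold, Pdgfra, with ATATGTA, fell 1.33-fold and Dpt (-0.24) was chosen after its values were seen. Lum had adjusted p from 0.0882 to 0.13 without each library other than siSirt7 replicate 3, 0.103 after quantile normalization, 0.0502 with no filter, 0.0884 without the trend and robust options and 0.111 for its transcript alone, and Pdgfra had 0.0559 without siScrambled replicate 3. Of 5 Schwann cell markers, 2 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.181). Mbp (5.64 and 4.51 FPKM) and Sox10 (1.596 and 1.01 FPKM) lost their calls without any 1 of the 6 libraries, with adjusted p from 0.0555 to 0.0986 and from 0.0757 to 0.127. Their main transcripts had 0.115 and 0.195, and Sox10 had 0.0514 with a pseudocount of 0.1 and 0.0936 after quantile normalization. Too few of the other marker lists were measured for a list test. Of 2 muscle markers tested, the troponin Tnnt2 fell from 30.7 ± 1.63 to 15.7 ± 1.09 FPKM (log2 fold change -0.93). The other muscle marker was not called and leaned upward, as the list mean was -0.31. Of 2 adipocyte markers, Pparg rose from 3.11 ± 0.56 to 5.09 ± 0.10 FPKM (log2 fold change 0.58, transcript alone limma adjusted p = 0.0552). The other adipocyte marker was not called and leaned downward, as the list mean was 0.24. Both lists had equal numbers adjusted over the list alone. The only endothelial marker tested, Erg (3.96 and 3.29 FPKM), and both macrophage markers tested, Lyz2 (18.0 and 18.7 FPKM) among them, were not called by limma, also adjusted over the list alone, and 0 of these 3 genes had an unadjusted p under 0.05. The table lists 0 of the 9 lymphocyte and 0 of the 6 erythroid markers.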

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

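The alternative that leaves out genes holding the 3' UTR words was chosen only after the result was seen; the others were planned. The 2736 genes changed became 1493 with single transcripts (780 higher, 729 lower), and 1670 without the word genes (646 lower, 63 at least 2-fold), where only 7804 genes were tested. With a pseudocount of 0.1, 216 genes changed at least 2-fold. For single transcripts and the pseudocount the cause was not tested. With 1 library left out, which leaves fewer samples, 1853 to 2222 genes were called, 953 to 1105 higher and 900 to 1117 lower (900 without siScrambled replicate 2), 95 to 110 at least 2-fold, and 1770 to 2043 of them were shared with the 2736, with 0 changes of sign. The replicate number as a block gave 1927 genes, 1834 of them shared. Of 15 lists past camera's threshold, 0 were past it with an estimated correlation and 15 with fry, which called 23 and compares no list with other genes. Past fry's threshold but not camera's were 8 lists, with fry adjusted p from 0.00138 to 0.0423. They were collagen and matrix, matrix proteases, osteogenic genes, synthetic smooth muscle, mitochondrial ribosomal proteins, TGF-beta, YAP and SRF, and Schwann cell markers. With 1 library left out, 11 to 14 lists were called. Sirt7 kept its direction in each alternative that gave it a value, from -1.28 to -1.65 with 1 library left out, with -2.27 at a pseudocount of 0.1 and -1.30 for its main transcript, which lost the call (adjusted p = 0.0697); a mean of at least 5 FPKM left no value for it. The main Kif20a transcript reversed to 1.30 (SE 1.08, adjusted p = 0.562), and the cause was not tested. Of 100 named genes called, 87 kept their call with each library left out, 81 with single transcripts and 88 with the block, which ended the calls of Bmp4, Cox6c, Lum, Mbp, Mrpl16, Mrpl45, Ndufa4, Phgdh, Sox10, Tnfrsf11b, Upk3b and Zdhhc21 (adjusted p from 0.0533 to 0.0882). The median of genes with ATATGTAA lay between -0.26 and -0.20 over 14 alternatives. Without counts, what depth limits cannot be given.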

Other observations

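Of the tests below, the scaling test of the NRF2 rise and the alternative that leaves out genes with the 3' UTR words were chosen only after the result was seen. The tests that look for these words in regulators and in mitotic genes were written after the words had been seen. Genes in this paragraph and the next were also chosen after their values were seen. Apart from G6pdx, a member of the NRF2 list, they belong to no list fixed beforehand, and they stand for themselves, not for a pathway. The glutathione S-transferase Gstm1 went from 29.4 ± 2.52 to 61.9 ± 1.07 FPKM, biliverdin reductase Blvrb from 19.6 ± 0.68 to 41.7 ± 1.29 and isocitrate dehydrogenase Idh1 from 30.96 ± 0.91 to 59.7 ± 1.26 (SD, n = 3; limma adjusted p from 0.000103 to 0.000296). The pentose phosphate enzymes G6pdx and Pgd rose with log2 fold changes of 0.81 and 0.94, and Tkt was at 21.2 and 32.0 FPKM (adjusted p = 0.0656). The transcript of NRF2 itself, Nfe2l2, went from 47.5 ± 1.11 to 65.1 ± 1.21 FPKM, and those of the small Maf proteins Mafg and Maff rose with log2 fold changes of 0.45 and 0.35. Metallothionein Mt1 went from 128.4 ± 18.5 to 297.8 ± 31.7 FPKM.

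Tissue factor (F3), which starts coagulation, went from 93.2 ± 1.69 to 195.7 ± 2.89 FPKM, the thrombin receptor F2r from 93.1 ± 0.89 to 215.6 ± 1.74 and the retinaldehyde dehydrogenase Aldh1a3 from 20.7 ± 1.19 to 61.0 ± 1.69 (SD, n = 3; limma adjusted p from 3.66e-05 to 7.6e-05).

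The fall of genes with ATATGTA in their 3' UTR is consistent with off-target silencing through an siRNA seed. The word was tied to lower fold changes (t = -19.55, against -5.10 in 100 shuffles). Medians were 0.01 with TATGTA alone, -0.05 and -0.11 with the words of 7 bases and -0.23 with ATATGTAA. These medians are no separate evidence, because the words were picked from the same fold changes and 3' UTR length was not adjusted for. ATATGTA lies in the Sirt7 coding sequence, as a guide against Sirt7 with that seed would need. By chance, 9.98% of the words tested occur in the main Sirt7 transcript and 26.0% in any, and TATGTAA (t = -16.1) and ATATGTAA occur in none, which does not count against a seed because the A at their end lies opposite the first guide base and need not match the target. The siRNA sequences were not used here, and an endogenous microRNA or RNA-binding protein that reads the same word was not tested. Loss of Sirt7 and effects of either siRNA are confounded in this design. The rise of genes with CGGAGAA was not tested for a cause. A rise with siSirt7 is also a fall with siScrambled, and the design cannot tell these apart. In the separate fit without genes that hold the words or have no matched 3' UTR, 646 of 7804 genes were called lower. The 2736 changed genes came from the real split, the highest of the other splits gave 1, and 10 splits are too few for a share under 0.05, counting the real split as the 1 with as many. A trend on GC content or length is argued against as the whole cause, since 92.1% of called genes stayed past the threshold with the same sign after its removal.

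For the rise of NRF2 antioxidant genes, scaling between libraries is argued against, because the list's median was at least 0.71 after median-of-ratios scaling and quantile normalization. Loss of Keap1 transcript, which encodes the NRF2 inhibitor, stays open, with a log2 fold change of -0.12 (95% interval -0.51 to 0.27). Seed sites in the lowered regulators Cul3 or Bach1 may contribute: Cul3 (log2 fold change -0.45, adjusted p = 0.00692), part of the ligase that degrades NRF2, and Bach1 (-0.44, adjusted p = 0.0157), a repressor of Hmox1, both hold ATATGTA, so 2 of 2 had a site. This is weak evidence, since both genes were chosen after their values were seen and 45.4% of all lower genes hold ATATGTA or TATGTAA. Keap1 was likewise chosen after its values were seen. Loss of Sirt7 itself remains an open, untested explanation.

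For the fall of mitotic genes, seed sites in the mitotic genes themselves are argued against as the whole cause, because the members without ATATGTA or TATGTAA had a median of -0.87 and all 14 were lower. A 3' UTR site of either word in the lowered cell cycle gene Ccnd1 is argued against as well, with 0 sites in its annotated 3' UTR. This does not cover shorter matches or sites in its coding part. Sites in other regulators and the loss of Sirt7 itself stay open, and no biological explanation could be tested apart from the siRNA.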
